A study of Homo sapiens with 3 samples.

How the data were processed

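Gene expression was measured on 3 single-channel oligonucleotide arrays, a human Affymetrix design, per the header of the probe annotation. Each array held RNA from 1 culture of TE 353.Sk, an established cell line from normal human skin that the submitters call basal cells. Per the labels' protocols, cultures at 80% confluence were exposed to a source of ultraviolet light (UV) with its maximum at 254 nm, at settings of 0, 20 or 40 mJ. The labels give the dose in mJ without an area. Medium was returned and total RNA was taken 24 hours later, and 5 µg of it was labelled for each array with the array maker's standard eukaryotic procedure. The groups were the 3 doses, with 1 array each, taken from the sample titles.

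The deposited values are intensity, that is, linear probe-set signals, with 22283 probe sets per array. The software that made the signal was not given in the sources used here, and no detection calls were used. The authors had already brought the arrays to nearly the same level, since the deposited intensity values had 2% trimmed means of 2501, 2501 and 2501 at 0, 20 and 40 mJ. A single factor per array made them equal. The medians differed, at 769.5, 588.3 and 615.6, and so did the 99th percentiles, at 52129.8, 85109 and 104652. Values ran from 0.8 to 291481 over the 3 arrays.

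Of the probe sets, 68 were controls of the array maker and were left out of the comparisons after scaling. Among the other 22215, the annotation table (dated 2016) names 1 gene for 19065, several genes for 1043 and none for 2107. Symbols were updated through the gene number with RefSeq's table for assembly GRCh38.p14, used for names alone, in which 19053 of the 19065 were found. Genes were named only from probe sets with 1 gene. Each gene was represented by the probe set with the highest mean signal, which left 11963 genes.

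Scaled signals under a floor of 410.5, the 40th percentile of all values of the 3 arrays, were set to the floor before log2 was taken. Values at the floor have no order, and a fold against the floor is given as a lower bound ("at least"). The 9207 genes above the floor on at least 1 array were compared. A gene was counted as higher or lower where its log2 difference was at least 1 in size, that is, 2-fold.

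With 1 array per dose there were no replicates, so no test was run and no p-value is given. Every difference compares arrays, not conditions, and the number of arrays limits the precision. As a partial measure of technical spread, the 3025 genes with several probe sets above the floor were used. The SD between probe sets of one gene was 0.74 at 20 against 0 mJ, 0.90 at 40 against 0 mJ and 0.45 at 40 against 20 mJ. This spread includes true differences between transcript forms and leaves out differences between cultures.

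For 26 gene lists, of which 18 were pathways and 8 were cell type markers, the median log2 difference of the measured members was set among 10000 random lists of the same size. The random lists were matched on mean log2 signal in 20 bins. The percentile describes these arrays and is not a test. Members without a probe set of their own were not analysed here.

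Both doses were compared with the same 0 mJ array, so unchanged arrays were simulated 50 times around that array. The noise came from the differences between the 20 and 40 mJ arrays. It holds any true difference between those doses and does not measure how the 0 mJ culture or its RNA varies, so it does not bound chance sharing. The steps from signal to counts were tested on simulated data for 20 against 0 mJ, run on 11963 genes. The changed genes were drawn from genes with a 0 mJ signal several times the floor, so the shares found do not cover genes near it. Of 50 genes given a log2 change of 2, 98.0% were counted as higher, and of 50 given -2, 100% were counted as lower. For changes of 1.5 and -1.5, 84.0% of 50 genes were counted in each direction. Of 8791 simulated unchanged genes, 564 (6.42%) were counted.

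The lists, the floor, the scaling, the fold and all alternatives except one were fixed before the data were examined. So was the rule for the genes named. It takes the 8 genes with the highest and the 8 with the lowest difference at each dose, among counted genes with the same sign at the other dose. It adds up to 4 counted members of each list (or 2 measured members where none was counted), a set of well-known UV response genes, and the 6 genes highest and the 6 lowest at 40 against 20 mJ. Genes linked to the Y chromosome and XIST were left out.

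The alternatives were floors at the 20th and 60th percentiles, the deposited values without scaling, one median for all arrays, quantile normalization and cyclic loess (limma 3.58.1 in R 4.3.3). Others were the mean of a gene's probe sets, only probe sets without an _s_at or _x_at suffix, and thresholds of 1.5-fold and 3-fold. A further call needed at least 2 probe sets above the floor, all of which changed alike by at least 1.5-fold. Scaling to 9 bacterial and phage spike-in probe sets was added after the data were seen. It does not measure RNA per cell, since 5 µg of RNA was labelled for each array. The floor stayed at 410.5 after this scaling had lowered both UV arrays, which left 8517 genes above it on at least 1 array. More values then lay at the floor, so medians and differences with this scaling can be pulled toward 0. The test of 5' loss, measured relative to 3' signal, also used a control transcript that is not reported here, and its outcome for mitosis and TGF-beta response genes depended on that control. Other steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.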

Results

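The series asked which genes change in cultured human skin cells after UV light. TE 353.Sk cells received 0, 20 or 40 mJ of 254 nm UV and their RNA was measured 24 hours later, on 1 array per dose. No dose was replicated. Of 11963 genes, 8222 were above the floor at 0 mJ, 7886 at 20 mJ and 8081 at 40 mJ.

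Fibroblast genes were present in the cultures at every dose. All 19 fibroblast markers with a probe set (such as COL1A1, PDGFRA and CDH11) were above the floor on each array, as were 8 of 10 smooth muscle and myofibroblast markers. Of 20 basal keratinocyte markers, only 13 had a probe set of their own, and of these 5, 4 and 6 were above the floor at 0, 20 and 40 mJ. For differentiated keratinocyte markers the numbers were 4, 4 and 6 of 16, and for simple epithelium markers 5, 5 and 6 of 9. Melanocyte markers numbered 1, 2 and 4 of 8, endothelial markers 3, 3 and 4 of 8, and leukocyte markers 5, 4 and 3 of 10.

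At 20 mJ, genes of cell division and of TGF-beta signalling were lower than at 0 mJ, while genes of mitochondrial respiration were higher. Ribosomal protein genes were higher too, but not with cyclic loess. In all, 1146 genes were at least 2-fold higher and 1609 at least 2-fold lower, out of 9207. Among the most reduced genes were NET1 (at least 27.7-fold lower), the mesenchymal transcription factor PRRX1 (22.0-fold) and the growth factor FGF5 (20.7-fold). The amino acid transporter SLC38A2 was 18.5-fold lower and MAT2A, which makes S-adenosylmethionine, 13.9-fold lower. APC, a regulator of Wnt signalling, was at least 13.6-fold lower, and SMAD7 and RAB23 were at least 13.3- and 13.0-fold lower. Among the most increased genes were the ribosomal protein gene RPS9 (8.84-fold), NUDT1, which clears oxidized nucleotides (7.52-fold), and CCHCR1 (at least 7.33-fold). The stress-induced gene NUPR1 was 6.72-fold higher, CIAO3 at least 6.61-fold and CFAP410 6.58-fold. These are values of the brightest probe set, and for some of these genes other probe sets above the floor differed less. The weakest was at -2.54 for NET1, -2.14 for FGF5, -2.32 for MAT2A, -0.63 for APC, 1.57 for RPS9 and 1.13 for CCHCR1, and another for CFAP410 was 2.20-fold higher. Of 46 counted named genes with several such probe sets at 20 mJ, 32 were at least 2-fold different on every one. In 23 the weakest was smaller by over 1.5 times, and in 2 it showed no difference or the other direction. Among genes named below, the weakest was at -0.24 for DUSP1 and -0.36 for MCL1.

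HBE1, an embryonic globin gene, was 42.8-fold higher at 20 mJ and FOLR1, a folate receptor gene, 14.3-fold. Each value rested on 1 probe set. The other HBE1 probe set stayed below the floor on all 3 arrays, and the other FOLR1 probe set was 1.96-fold higher at 20 mJ.

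Mitosis genes were lower as a group at 20 mJ, with 17 of 38 at least 2-fold lower and 1 higher. Their median log2 difference was -0.92, at percentile 0.05 among matched random lists, and it lay below 0 under every scaling tried. CDK1, the kinase that drives entry into mitosis, was at -2.41, the cytokinesis factor ECT2 and the spindle motor KIF11 at -2.28 each, and PBK at -1.73. CCNB1, the cyclin partner of CDK1, was at -0.94, short of 2-fold. DNA replication genes were mixed, with 6 of 35 lower and 3 higher. RFC3, a clamp loader subunit, was at -2.30 and the replication clamp PCNA at -1.19, while GINS2 was at least 5.03-fold higher.

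TGF-beta response genes had a median of -1.47 at 20 mJ, below all 10000 matched lists and below 0 under every scaling, with 10 of 17 lower and 0 higher. The secreted matrix regulator CCN2 was at -2.88, the inhibitor of differentiation ID1 at -2.63 and the receptor TGFBR2 at -1.81. Unfolded protein and amino acid stress genes had a median of -0.73 (percentile 0.06, below 0 under every scaling), with 7 of 21 lower and 2 higher. The endoplasmic reticulum degradation factors SEL1L and HERPUD1 were at -2.32 and -1.76, and the chaperone cofactor DNAJB9 at -2.09. Among immediate early genes, which respond to growth signals, 10 of 21 were lower and 4 higher, with a median of -0.61 at percentile 1.74, below 0 under every scaling but at -0.04 and percentile 5.56 with one median for all arrays. The phosphatase genes DUSP1 and DUSP5 were at -2.74 and -2.02, DUSP6 was at least 9.79-fold lower, and MYC was at -2.62. Beside these lower groups, the 3' over 5' signal ratio of the control transcript of beta-actin was 0.987 at 0 mJ and 4.00 at 20 mJ. For GAPDH it was 0.788 and 1.09.

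Oxidative phosphorylation genes were higher as a group at 20 mJ under every scaling, and ribosomal protein genes were higher under some. Of 42 ribosomal protein genes, 21 were at least 2-fold higher and 0 lower, with a median of 0.998 at percentile 97.9. With cyclic loess 1 was higher and the median was 0.00 (percentile 63.2), and with quantile normalization 3 were and it was 0.30 (percentile 77.7). RPS21 was at 1.63, RPL34 at 1.54 and RPL14 at 1.48. Of 49 oxidative phosphorylation genes, 29 were higher and 0 lower, with a median of 1.15 at percentile 99.99, and with cyclic loess 12 were higher and the median was 0.58, above all matched lists. The complex I genes NDUFA3, NDUFS6 and NDUFS7 were at 2.34, 1.92 and 1.92, and the complex III gene UQCRB at 1.84. Bright genes were higher in general, since among 10 groups of genes split by mean signal the brightest had a median difference of 0.68 and group 4 one of -0.40. The 9 spike-in probe sets used for scaling were 1.45-fold higher at 20 mJ than at 0 mJ.

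Interferon-stimulated genes had a median of 0.30 at 20 mJ (percentile 98.9), which was -0.08 with spike-in scaling and lay at percentile 95.2 with cyclic loess, with 6 of 30 higher and 1 lower. The ubiquitin-like modifier ISG15 was at 2.34, the immunoproteasome genes PSMB8 and PSMB9 at 2.04 and 1.62, and the transcription factor IRF7 at 1.67. Cytokine and NF-kB target genes went both ways, with 4 of 20 higher and 3 lower and a median of -0.14 (percentile 50.9, and 0.06 with one median for all arrays). The neutrophil chemokine genes CXCL2 and CXCL3 were at least 5.09- and 4.50-fold higher and CXCL1 was at 1.92, while TNFAIP3, an inhibitor of NF-kB, was at -2.28. IL6 was at 0.85, under 2-fold. CXCL8 was at -0.38 on its brightest probe set, while its other probe set above the floor was 2.01-fold higher.

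The p53 target genes showed no common direction at 20 mJ, with 5 of 25 higher and 7 lower and a median of 0.04 (percentile 52.1). PLK2 was at -2.69, ZMAT3 at -2.18, and SESN1 and the death receptor gene FAS at -1.79 each. CDKN1A, the cell cycle inhibitor p21, was at 0.47, MDM2 at 0.25 and GADD45A at 0.83, all short of 2-fold, and CDKN1A lay below 0 with spike-in scaling and cyclic loess and MDM2 with spike-in scaling. Nucleotide excision repair genes, which remove UV lesions, had 3 of 24 higher and 2 lower, with a median of 0.13 (percentile 68.5). The incision factor ERCC1 was at 2.04, the lesion sensor DDB2 at 1.68 and the TFIIH subunit GTF2H5 at 1.52, while RPA1, which binds single-stranded DNA, was at -1.13. XPC, another lesion sensor, was at 0.77.

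Collagen and extracellular matrix genes had a median near 0 at 20 mJ (-0.02), yet this was at percentile 0.04, since matched lists of bright genes were higher. It was 0.37 with one median for all arrays, -0.64 with quantile normalization, -0.67 with cyclic loess and -0.56 with spike-in scaling. Of 35, 7 were lower and 4 higher (10 and 1 with cyclic loess), and CCN1, THBS1 and COL4A1 were at -3.15, -1.94 and -1.53. COL1A1, the main collagen chain of skin, was at 0.43 on its brightest probe set, below 0 with quantile, loess and spike-in scaling, while another of its probe sets read 51157 at 0 mJ and 3644 at 20 mJ. Matrix protease and inhibitor genes had 6 of 21 lower and 1 higher (median -0.09, percentile 3.14, and 0.29 with one median for all arrays), with ADAMTS1 at -2.41, the plasminogen activator PLAT at -1.22 and MMP16 at least 2.89-fold lower. The collagenase gene MMP1 was at 0.99 and MMP3 at -0.09, the latter above 0 with one median for all arrays.

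The remaining pathway lists held few counted genes at 20 mJ or went both ways. Oxidative stress genes had 8 of 26 higher and 7 lower (median 0.30, percentile 30.8), with AKR1C3 at 2.19 and the glutathione and thioredoxin genes GCLC, SLC7A11 and TXNRD1 at -2.38, -2.19 and -2.19. Their direction depended on the scaling, since with cyclic loess 1 was higher and 7 lower, with a median of -0.43 at percentile 0.57, and with quantile normalization the median was -0.11. Heat shock genes had 1 of 13 lower and 0 higher (median -0.28, percentile 1.48, and 0.11 with one median for all arrays, and percentile 8.415 with cyclic loess), and the counted member was HSP90AB1 at -1.20. Apoptosis genes had 6 of 23 lower and 1 higher (median -0.15, percentile 19.7, and 0.24 with one median for all arrays), with the survival factor MCL1 at -2.19, BIRC2 at -1.57 and CASP8 at least 3.14-fold lower. Cholesterol synthesis genes had 4 of 16 higher and 2 lower (median 0.19, percentile 78.6), with HSD17B7 at 1.77 against INSIG1 at -2.22 and SC5D at -1.51. Glycolysis and hypoxia genes had 3 of 21 lower and 1 higher (median 0.33, percentile 40.2, but -0.06 with quantile normalization and -0.25 with cyclic loess), with BHLHE40 at least 8.90-fold lower and HK2 and SLC2A3 at -1.29 and -1.26.

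Among cell type markers at 20 mJ, the fibroblast list had a median of -0.00 (percentile 0.265), which was 0.38 with one median for all arrays, -0.59 with quantile normalization, -0.66 with cyclic loess and -0.54 with spike-in scaling. Of 19, 3 were lower, namely PRRX1, CDH11 at -1.87 and PDGFRA at -1.80, though another PDGFRA probe set above the floor was 1.93-fold higher. Differentiated keratinocyte markers had a median of 0.51 over 6 measured genes (percentile 98.3, but 0.04 with spike-in scaling), with KRT10 at 1.36. Simple epithelium markers had 0.40 over 7 (percentile 97.65), with KRT7 at 1.24. Over the same genes the median was 0 with spike-in scaling, where the middle member lay at the floor on both arrays. Their shift from matched lists reversed to -0.00959 with probe sets without a suffix. Basal keratinocyte markers had a median of 0.00 over 8 (percentile 69.8), with the integrin gene ITGA6 at -1.37. The smooth muscle list had a median of 0.40 over 8 genes (percentile 23.1, and below 0 with quantile, loess and spike-in scaling over the same genes), with TPM2 at 1.03. Medians were 0.00 over 4 melanocyte markers (percentile 68.8), -0.09 over 4 endothelial markers (percentile 62.7), of which EGFL7 was at 1.12, and 0.02 over 5 leukocyte markers (percentile 78.6).

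The share of counted genes that were higher at 20 mJ was 41.6%, and it became 66.7% with one median for all arrays, 57.0% with quantile normalization and 11.3% with spike-in scaling. Where all probe sets of a gene above the floor, and at least 2, had to change alike, 183 genes were higher and 440 lower. Genes with fewer such probe sets could not be counted under this rule. Among 26 lists, 7 lay below and 5 above the central 95% of matched lists, where 1.3 in all would for lists of unrelated genes. Some lists share members, such as CCN2, and genes of a list may vary together, so this number does not bound chance.

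At 40 mJ, mitosis and TGF-beta genes were again lower than at 0 mJ and respiratory genes higher, the last by little with spike-in scaling. Ribosomal protein genes stood apart from matched lists under some scalings only, and more genes passed 2-fold. There were 1626 genes higher and 2008 lower. PRRX1 was 33.1-fold lower, the actin-binding gene CNN3 22.3-fold, SLC38A2 22.1-fold and the growth factor FGF2 20.1-fold. NET1, AIDA and the serine synthesis gene PSAT1 were at least 27.7-, 22.0- and 18.8-fold lower. IL6ST, the shared receptor of the IL-6 family, was at -4.14 on its brightest probe set, while its 5 probe sets ran from -4.14 to -0.55. NUPR1 was 12.5-fold higher, RPS9 11.6-fold, CCHCR1 at least 10.6-fold, CFAP410 10.3-fold, NUDT1 9.03-fold and the pyroptosis gene GSDMD 8.92-fold. The weakest probe set above the floor was at -2.27 for NET1, 1.88 for RPS9 and 1.44 for CCHCR1. For CFAP410 it was at least 0.16, a lower bound because that probe set lay below the floor at 0 mJ. Of 50 counted named genes with several such probe sets, 33 were at least 2-fold different on every one. In 30 the weakest was smaller by over 1.5 times, and in 3 it showed no difference or the other direction. Among genes named below, the weakest was at -0.61 for DUSP1, -0.02 for MCL1 and -0.77 for SLC7A11. HBE1 and FOLR1 were 152.5- and 49.1-fold higher on 1 probe set each, while the other FOLR1 probe set was 1.53-fold higher.

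**Figure D1:**
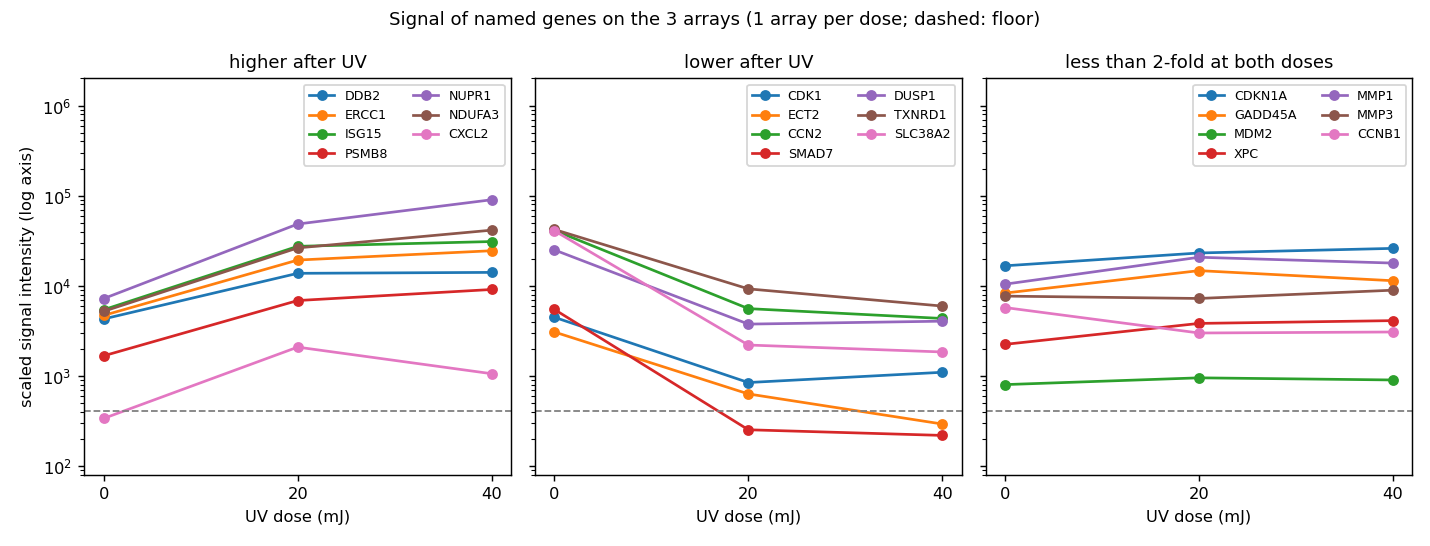
Scaled signal (vertical, log axis) of 21 named genes against UV dose (horizontal, mJ), with 1 array per dose and a dashed line at the floor of 410.5. DDB2 and ISG15 lay higher and CDK1 and CCN2 lower on both UV arrays than at 0 mJ, while CDKN1A and MDM2 stayed within 2-fold.

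Ribosomal protein genes were higher by a median of 1.53 at 40 mJ, above all 10000 matched lists, with 41 of 42 at least 2-fold higher. With cyclic loess 3 were higher and the median was 0.31, inside the matched range (percentile 93.2), with quantile normalization 4 were and it was 0.37 (percentile 86.7), and with spike-in scaling 3 were and it was 0.45. RPS21, RPL34 and RPL14 were at 2.19, 2.10 and 2.06. Oxidative phosphorylation genes had a median of 1.18 (percentile 99.04), with 30 of 49 higher and 1 lower. It was 0.68 with cyclic loess, with 18 higher and 2 lower, and 0.10 with spike-in scaling, with 9 higher and 6 lower. NDUFA3, NDUFS6, NDUFS7 and UQCRB were at 2.99, 2.60, 2.34 and 2.32. Of the 10 groups by mean signal, the brightest had a median of 0.82 and group 5 one of -0.36. The spike-in probe sets used for scaling were 2.12-fold higher than at 0 mJ.

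Mitosis genes had a median of -1.01 at 40 mJ (percentile 0.15, below 0 under every scaling), with 19 of 38 lower and 1 higher. CDK1 was at -2.03 and PBK at -2.24, and ECT2 and KIF11 were at least 7.49- and 6.35-fold lower. TGF-beta response genes had a median of -1.21 (percentile 0.12, below 0 under every scaling), with 10 of 17 lower and 1 higher, among them CCN2 at -3.25 and TGFBR2 at -2.55. Unfolded protein and amino acid stress genes had 9 of 21 lower and 3 higher (median -0.71, percentile 0.665, below 0 under every scaling), with SEL1L at -2.63 and DNAJB9 at -2.47. Immediate early genes had 8 of 21 lower and 5 higher (median -0.50, percentile 9.39), with DUSP1 at -2.63 and MYC at least 7.89-fold lower. The 3' over 5' ratios beside these groups were 8.06 for beta-actin and 1.53 for GAPDH.

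Collagen and extracellular matrix genes were lower at 40 mJ relative to matched lists, with a median of -0.27 (percentile 0.05) that became 0.05 with one median for all arrays and -0.95 with quantile normalization. It was lower again with cyclic loess, with 18 lower and 3 higher. Of 35, 12 were lower and 5 higher, with COL4A1 at -2.39, CCN1 at -2.20 and THBS1 at -2.10. COL1A1 was at 0.78 on its brightest probe set, below 0 with quantile, loess and spike-in scaling, and its probe sets ran from -3.66 to 0.78. The fibroblast list had a median of -0.17 (percentile 0.225, 0.15 with one median for all arrays and -0.75 with cyclic loess), with 5 of 19 lower and 2 higher (9 and 0 with cyclic loess), among them CDH11 at -3.13 and the surface protease FAP at -2.54. Matrix protease and inhibitor genes had 6 of 21 lower and 2 higher (median 0.02, percentile 13.3, but -0.14 with quantile normalization and -0.31 with cyclic loess), with the inhibitor TIMP3 at -2.60. MMP1 was at 0.78 and MMP3 at 0.22, both below 0 with spike-in scaling.

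Interferon-stimulated genes had a median of 0.46 at 40 mJ (percentile 98.5), which was -0.22 with spike-in scaling, with 8 of 30 higher and 2 lower, among them ISG15 at 2.51 and PSMB8 at 2.44. Cytokine and NF-kB target genes had 5 of 20 higher and 1 lower (median 0.13, percentile 80.8), with CXCL1 at 1.22 and TNFAIP3 at -2.34. The p53 target genes had 5 of 25 higher and 7 lower (median 0.17, percentile 61.8), with FAS at -2.12. CDKN1A was at 0.64, GADD45A at 0.45, MDM2 at 0.17, XPC at 0.87 and IL6 at 0.78, each below 0 with spike-in scaling. Nucleotide excision repair genes had 5 of 24 higher and 4 lower (median 0.09, percentile 58.1, and 9 higher and 3 lower with cyclic loess), with ERCC1 at 2.38, DDB2 at 1.72 and RPA1 at -2.10. DNA replication genes had 10 of 35 lower and 5 higher (median 0.03, percentile 61.2, and -1.06 with spike-in scaling), with RFC3 at -1.90 and POLD1 at 1.95.

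Of the other lists at 40 mJ, oxidative stress genes had 9 of 26 higher and 7 lower (median 0.11, percentile 9.62, but -0.20 with quantile normalization, and -0.31 with 2 higher and 9 lower with cyclic loess), with TXNRD1 at -2.82 and SLC7A11 at least 8.95-fold lower. Apoptosis genes had 5 of 23 lower and 2 higher (median -0.50, percentile 4.32), with BIRC2 at -2.26 and MCL1 at -2.11. Heat shock genes had 3 of 13 lower and 0 higher (median -0.14, percentile 7.84, and 0.18 with one median for all arrays), namely HSP90AB1 at -1.48, DNAJA1 at -1.15 and HSPH1 at -1.13. Cholesterol synthesis genes had 5 of 16 higher and 3 lower (median 0.38, percentile 85.4), with PMVK at 2.01 and INSIG1 at -1.97. Glycolysis and hypoxia genes had 4 of 21 higher and 4 lower (median 0.29, percentile 30.9, but -0.19 with quantile normalization, and -0.31 with 1 higher and 5 lower with cyclic loess), with PFKFB3 at least 3.31-fold lower. With spike-in scaling the medians of the p53, repair, DNA replication, cytokine, matrix protease, oxidative stress, cholesterol and glycolysis lists were below 0 at both doses. Simple epithelium markers had a median of 0.62 (percentile 97.75, percentile 92.1 with cyclic loess, and -0.03 with spike-in scaling), with KRT7 at 2.03 and MUC1 at 1.06, the latter also below 0 with spike-in scaling. Smooth muscle markers had 3 of 8 higher (median 0.67, percentile 40.2, and below 0 with quantile, loess and spike-in scaling over the same genes), namely TPM2, MYL9 and CNN1 at 1.41, 1.37 and 1.14.

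**Figure D2:**
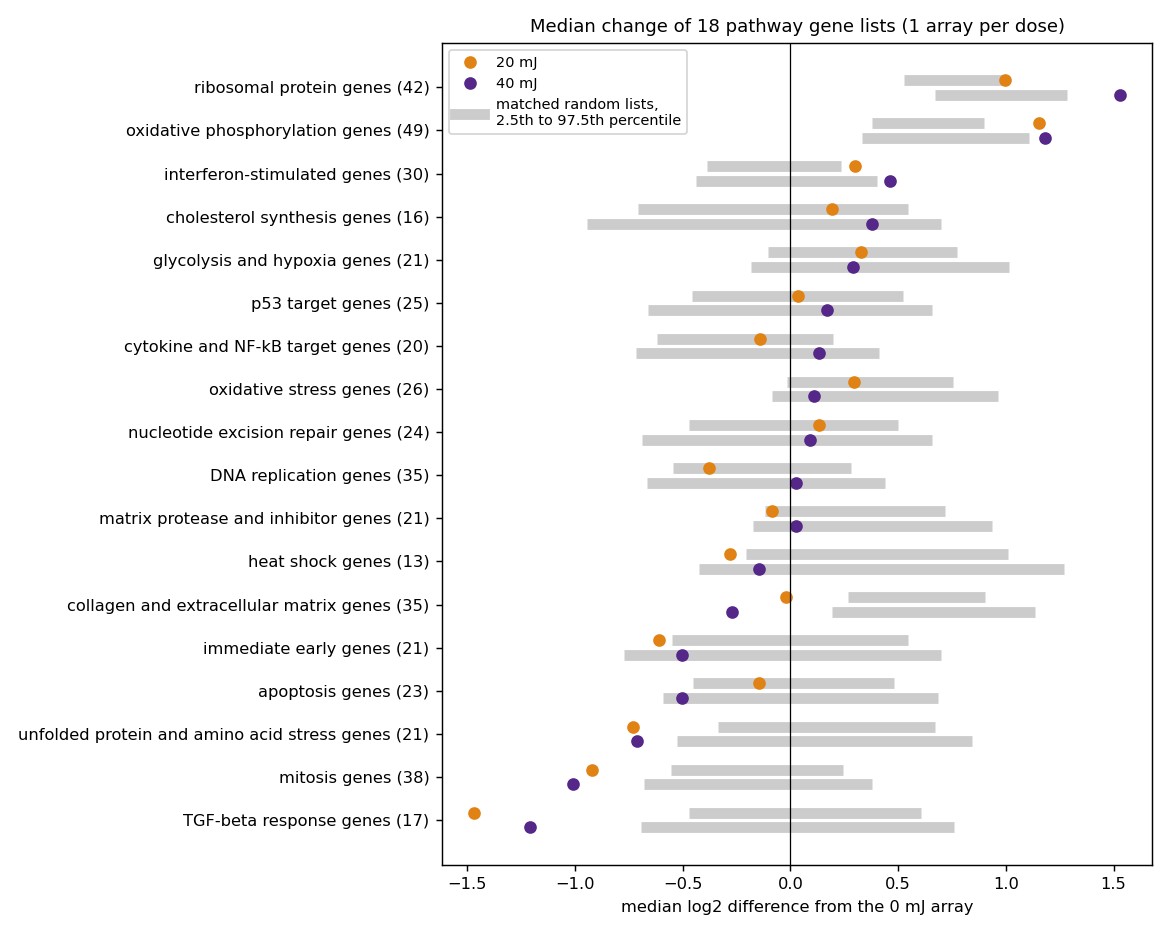
Median log2 difference from the 0 mJ array (horizontal) for 18 pathway gene lists (vertical, with the number of measured members), at 20 mJ (orange) and 40 mJ (purple). Grey bars span the central 95% of 10000 matched random lists, and TGF-beta response genes lay below their bars at -1.47 and -1.21.

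The keratinocyte, melanocyte, endothelial and leukocyte lists had 4 to 8 measured members each at 40 mJ. Medians were 0.28 for basal keratinocyte markers (percentile 92.5), 0.49 for differentiated keratinocyte markers (percentile 90.4), 0.39 for melanocyte markers (percentile 89.0), 0.10 for endothelial markers (percentile 65.1) and 0.28 for leukocyte markers (percentile 85.5), each 0 or below with spike-in scaling. Some melanocyte markers were above the floor on the 40 mJ array alone, so their rise is partly built in. ITGA6 was at -1.52, EGFL7 at 1.88 and CD14 at 1.16, while KRT10 was at 0.89 and MITF at 0.25, both below 0 with spike-in scaling, and OCA2 at least 1.80-fold higher.

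The share of counted genes that were higher at 40 mJ was 44.7%, and it became 61.5% with one median for all arrays, 57.2% with quantile normalization and 5.33% with spike-in scaling. With agreeing probe sets required, 267 genes were higher and 514 lower. Of 26 lists, 5 lay below and 4 above the central 95% of matched lists.

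The same genes stood out at both doses. Of the genes higher at 20 mJ, 90.7% were also higher at 40 mJ (1039 genes, among them DDB2, ISG15, NUPR1 and NDUFA3). Of those lower at 20 mJ, 90.7% were also lower at 40 mJ (1459 genes, among them CDK1, CCN2, SMAD7 and SLC38A2), and 0 genes were counted in opposite directions. Independent lists of these sizes would share 202 and 350.9 genes. Simulated unchanged arrays compared with one shared control gave 42.6 and 123 shared genes on average, with noise that holds no measure of how the 0 mJ culture or its RNA may vary. The log2 differences at the 2 doses correlated across genes at r = 0.92, against 0.50 in the simulation, and genes are not independent replicates. Their covariance was 1.11 against 0.143 simulated, a difference of 0.967, and part of any excess may come from the shared 0 mJ array.

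**Figure D3:**
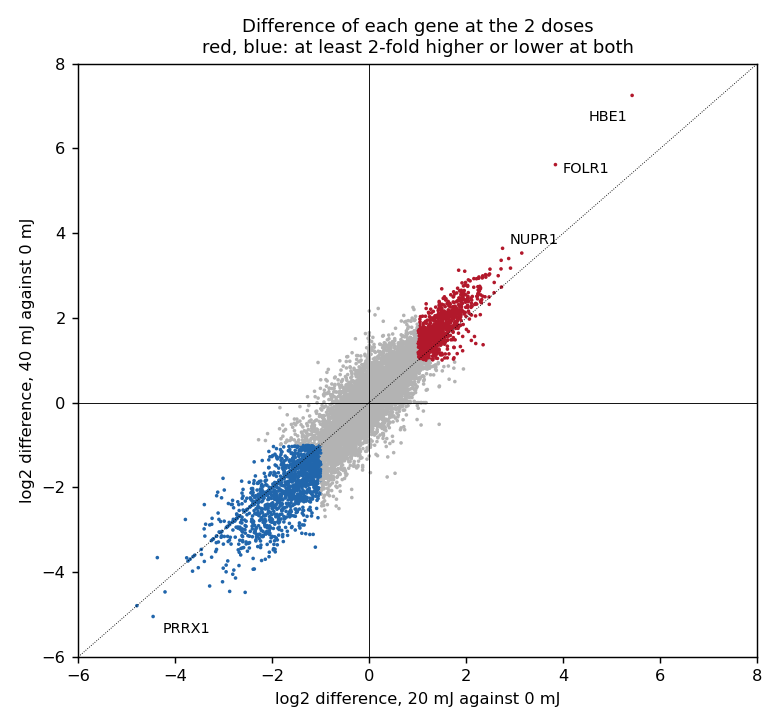
Log2 difference of each gene at 20 mJ (horizontal) and at 40 mJ (vertical), both against the 0 mJ array, with a dotted line of equal values. The 1039 genes at least 2-fold higher at both doses are red and the 1459 lower at both are blue, with HBE1 and FOLR1 at the upper right.

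Between 20 and 40 mJ far fewer genes differed, with 181 higher and 247 lower at 40 mJ. Of 154 counted genes with several probe sets above the floor, 40.9% changed in the same direction on all of them. That share was 82.3% at 20 and 75.9% at 40 against 0 mJ. Probe sets of one gene had only 0.169 of the variance in common between 20 and 40 mJ, so most such calls rest on single probe sets. Higher genes included NFKBIL1 (at least 4.48-fold), SPTBN4 (4.11-fold), RAP1GAP (at least 4.01-fold), THAP3 (3.87-fold), HBE1 (3.56-fold) and SPN (3.47-fold, while its other probe set was at 0.03). Lower genes included the death receptor family member TNFRSF21 (at least 4.92-fold), ELK2AP (at least 4.59-fold), SPDEF (4.36-fold on its brightest probe set, while its other one was at 0.52), MPPED1 and SNRNP40 (at least 3.87-fold each) and CNN3 (3.78-fold). Fibroblast markers had a median of -0.25 (percentile 0.125), with CDH11 at -1.26 and FAP at -1.62, and collagen and extracellular matrix genes -0.34, below all 10000 matched lists, and both medians were below 0 under every scaling. The matrix inhibitor gene TIMP3 was at -1.42. Ribosomal protein genes had a median of 0.52, above all 10000 matched lists, and of 0.30 with cyclic loess, also above all matched lists. The median was 0.07 with quantile normalization and -0.02 with spike-in scaling. Oxidative stress genes had a median of -0.15 (percentile 1.07, and 3.835 with cyclic loess). Melanocyte markers had a median of 0.59 over 4 genes (percentile 98.55, and 94.0 with cyclic loess), which was 0 with spike-in scaling. Of these, 1, 2 and 4 were above the floor at 0, 20 and 40 mJ. Some thus entered the list through the 40 mJ array alone, and a rise there is partly built in.

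The mitosis and TGF-beta lists were level between the UV doses, with medians of -0.00 (percentile 50.2) and 0.06 (percentile 70.2). With spike-in scaling these medians were -0.47 and -0.10. That scaling lowers every signal by 0.55 more at 40 than at 20 mJ, and values set to the floor made both falls smaller. DDB2 was at 0.03, PCNA at 0.03, CCNB1 at 0.04, CDKN1A at 0.17, ISG15 at 0.18 and MMP1 at -0.22, all smaller than the SD of 0.45 between probe sets of one gene. With spike-in scaling DDB2, PCNA and CCNB1 were at -0.51 each, MMP1 at -0.76, CDKN1A at -0.38 and ISG15 at -0.37, of which the first 4 exceed that SD. Simulated unchanged arrays gave 595 counted genes, above the 428 observed, with the simulated noise itself taken from these 2 arrays. Genes higher made up 42.3% of the counted genes, and 0.590% with spike-in scaling.

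Across the 9207 genes, log2 signals correlated at 0.97 between 20 and 40 mJ, 0.86 between 0 and 20 mJ and 0.79 between 0 and 40 mJ. The control probe sets moved with dose as well, so that the 3' over 5' ratio of beta-actin was 0.987, 4.00 and 8.06.

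**Figure D4:**
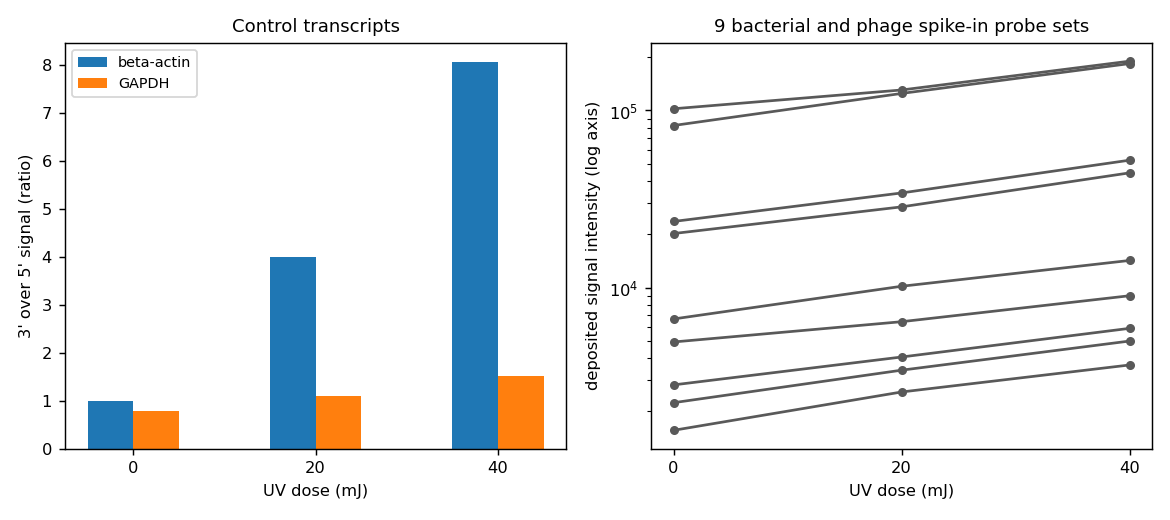
Left, 3' over 5' signal ratio (vertical) of the beta-actin and GAPDH control transcripts at each UV dose (horizontal, mJ). Right, deposited signal (vertical, log axis) of the 9 spike-in probe sets used for scaling at each dose, each line 1 probe set, 1.45-fold higher on average at 20 mJ and 2.12-fold at 40 mJ than at 0 mJ.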

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

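All tests of explanations given here were chosen after the results were seen. The array maker's control probe sets, which enter no comparison, gave different values on the UV arrays than at 0 mJ. The 3' over 5' signal ratio was 0.987 for beta-actin and 0.788 for GAPDH at 0 mJ. At 20 mJ these ratios were 4.00 and 1.09, and at 40 mJ 8.06 and 1.53. The 5' signal itself was lower for beta-actin (0.283 and 0.133 of its 0 mJ value at 20 and 40 mJ) but not for GAPDH (1.20- and 1.23-fold higher). The 9 bacterial and phage spike-in probe sets used for scaling were 1.45-fold higher at 20 mJ and 2.12-fold higher at 40 mJ, with log2 SDs between them of 0.12 at each dose. Another 9 spike-in probe sets ran from 1.23- to 1.91-fold at 20 mJ and from 1.64- to 3.01-fold at 40 mJ, with wider log2 SDs of 0.20 and 0.29. A control probe set for 28S ribosomal RNA was 40.6-fold higher at 20 mJ and 65.1-fold at 40 mJ, and one for 18S ribosomal RNA 43.1- and 13.0-fold. The ribosomal RNA controls had no common direction, since another 28S probe set was at 0.835 and 0.188 of its 0 mJ signal at 20 and 40 mJ, a further one at 0.359 and 0.0242, and another 18S probe set at 0.975 and 0.275.

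The first pattern weighed is that ribosomal protein and oxidative phosphorylation genes were higher after UV while bright genes were higher in general. An intensity-dependent stretch of the signal was tested by cyclic loess, which removes such a trend. It left the ribosomal protein median at 0.31 at 40 mJ and 0.00 at 20 mJ, inside the range of matched lists (percentiles 93.2 and 63.2), so that a stretch may account for most of that group's difference from 0 mJ. At 40 against 20 mJ the ribosomal protein median stayed at 0.30 with cyclic loess, above all matched lists. It was 0.07 with quantile normalization and -0.02 with spike-in scaling, so whether a stretch accounts for all of that step stays open. Cyclic loess left oxidative phosphorylation genes at 0.68 at 40 mJ and 0.58 at 20 mJ, above the central 95% of matched lists at both doses, which argues against a stretch as the whole cause there. A response of respiratory genes to UV stays open as a hypothesis, as does any difference between single cultures, RNA preparations or arrays.

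The second pattern is that mitosis, TGF-beta response, and collagen and matrix genes were lower while 5' signal fell relative to 3' signal in control transcripts. If loss of 5' parts were the cause, these lists would be lower again at 40 than at 20 mJ, as the controls' 5' over 3' ratios were. Collagen and matrix genes were, with a matched shift of -0.42 (SD of random lists 0.08) after -0.60 at the first step, a size that the controls' ratios would give, so 5' loss may contribute. Mitosis genes shifted by 0.000471 after -0.78, where the ratios of beta-actin and GAPDH would give -0.39 and -0.80, and TGF-beta response genes by 0.0598 after -1.505, where they would give -0.75 and -1.55. The shifts that beta-actin and GAPDH would give lie well below those seen, but the test also used a control that is not reported here. The controls differed in how much 5' signal they lost, relative to 3' signal, between the UV doses. With all of them, 5' loss and a UV response cannot be told apart for these lists.

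The third pattern is that the 0 mJ array stood apart from both UV arrays. Noise of single probe sets is argued against, since probe sets of one gene shared 0.511 of the variance of log2 differences at 40 mJ and 0.534 at 20 mJ. Array-wide scaling is argued against too, since the fewest genes that any single factor per array left counted were 10.8 times as many at 40 against 0 mJ as at 40 against 20 mJ, and 8.06 times as many at 20 against 0 mJ (2916 and 2175 genes, with 270 at 40 against 20 mJ, of the 6976 genes above the floor on all arrays). Neither test covers an array difference that changes with signal, and bright genes were higher in general. What stays open is the UV itself against any other difference of the 0 mJ culture, its RNA or its array from the others. With 1 array per dose these cannot be separated.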

How the results depend on the processing

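Spike-in scaling was chosen after the data were seen; all other settings were planned. No paired analysis was possible because each dose has 1 array, and for the same reason no array could be left out and no other split of the arrays could be made. Of 96 alternative counts, 50 stayed within 1.5 times the main count and 46 did not, and every count did with cyclic loess, quantile normalization and the values as deposited. Counts follow in the order higher and lower at 20 against 0 mJ, at 40 against 0 mJ, at 40 against 20 mJ, then at both doses. Spike-in scaling gave 335, 2628, 214, 3802, 6, 1011, 180 and 2578. A 3-fold threshold gave 303, 759, 637, 1115, 14, 22, 272 and 680. A 1.5-fold threshold gave 2186, 2542, 2709, 2812, 997, 992, 1894 and 2270. Agreeing probe sets, which need genes with at least 2, gave 183, 440, 267, 514, 6, 14, 155 and 363. One median gave 2022 and 1010 at 20 mJ and 1731 and 913 at both doses. Only probe sets without a suffix, which leave 8361 genes, gave 662 higher at 20 mJ, 931 higher at 40 mJ, 108 higher and 159 lower at 40 against 20 mJ, and 597 higher at both doses. At 40 against 20 mJ, higher and lower counts were 723 and 717 with the floor at the 20th percentile, 31 and 102 at the 60th, and 105 and 151 with the mean of all probe sets. The median difference of all genes, -0.00 at 20 mJ and 0.01 at 40 mJ, moved to 0.24 and 0.26 with one median, 0.11 and 0.19 with quantile normalization, 0.03 and 0.11 with cyclic loess, and -0.50 and -0.83 with spike-in scaling. Of 702 alternative list shifts, 593 stayed within 1 SD of random lists, 108 moved by more and 1 reversed, which counts only lists outside the central 95% of matched lists. This was the simple epithelium list at 20 mJ (-0.00959 with probe sets without a suffix), and another 45 shifts, of lists inside that range, also had the other sign. Of 2132 alternative values of named genes, 1867 stayed within the SD between probe sets, 264 moved by more and 1 reversed among genes counted at 2-fold, which was MUC1 at 40 mJ (-0.0251 with spike-in scaling). Another 35 values of genes not counted also had the other sign, and of all 36 such values 18 came from spike-in scaling. The cause of these changes was not tested. Of the 2755 genes counted at 20 mJ, 2036 kept their call with cyclic loess and 1943 with spike-in scaling, and of the 3634 at 40 mJ, 2959 and 2222 did. Where signals lie near the floor, differences are lower bounds or are lost, and 40 against 20 mJ depends most on the floor.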

Other observations

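Symbol families were screened after the data were seen, 22 in all, and those described here were picked after their values were seen. Members of the fixed lists were not removed from them. Kinesin genes share members such as KIF11 with the mitosis list, and SMAD genes share SMAD7 with the TGF-beta list, so these results are not separate. Mitochondrial ribosomal protein genes were higher after UV, with 23 of 49 at least 2-fold higher and 0 lower at 20 mJ and 26 higher and 2 lower at 40 mJ. Their medians were 0.94 and 1.02 (percentiles 100 and 99.99), 0.92 and 1.11 with cyclic loess, and 0.41 and -0.06 with spike-in scaling. MRPL23 was at 2.40 and 3.02, MRPL33 at 2.24 and 2.56, and MRPS11 at 1.98 and 2.77, while MRPL3 was at -0.43 and -1.14. Glutathione S-transferase genes, which detoxify reactive compounds, had 5 of 14 higher and 0 lower at each dose, with medians of 0.72 and 0.75 (percentiles 97.7 and 94.1, and -0.24 at 40 mJ with spike-in scaling). GSTK1 was at 1.56 and 1.77 and GSTO1 at 1.33 and 1.70.

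Genes of heterogeneous nuclear ribonucleoproteins, which package and splice nuclear RNA, were lower, with 6 of 18 at 20 mJ and 11 of 18 at 40 mJ and 0 higher at either dose. Their medians were -0.67 and -1.21 (percentiles 0.29 and 0.05), below 0 under every scaling, and the 40 mJ array was lower than the 20 mJ array by a median of -0.47. Over the same arrays the 3' over 5' ratio of beta-actin rose (0.987, 4.00 and 8.06), and loss of 5' parts was not tested for this family. HNRNPR was at -1.87 and -2.69, HNRNPA0 at -1.85 and -2.29 and HNRNPH1 at -1.02 and -2.13, while HNRNPD was at 0.19 and 0.10. Kinesin genes, which encode motor proteins, had 7 of 23 lower at 20 mJ and 10 at 40 mJ, with medians of -0.78 and -0.67 (percentiles 1.58 and 5.79), below 0 under every scaling. Of the 22 families, 6 at 20 mJ and 3 at 40 mJ lay outside the central 95% of matched lists. The others among these were tubulin genes at 20 mJ (median -0.29 over 10, percentile 0.02, and 0.10 with one median for all arrays), forkhead genes at 20 mJ (-0.70 over 13, percentile 0.97) and SMAD genes at 40 mJ (-1.35 over 9, percentile 1.53), of which the forkhead and SMAD medians were below 0 under every scaling.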
